A study of Mus musculus with 21 samples.

How the data were processed

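Gene expression was measured on 21 Affymetrix mouse exon arrays, 1 per sample, hybridised with biotin-labelled cDNA made from total RNA of frozen cell pellets. The samples were mouse splenocyte cultures, grouped by the deposited sample titles into 3 reporter groups of 5 arrays and 2 knockout groups of 3 arrays. The deposited values are on the log2 scale and were summarised by the authors with RMA in Affymetrix Expression Console 1.2 on genome build mm8, per the submitters' processing notes. The deposited table holds 1 log2 value per transcript cluster and array for 23332 clusters, and 0 of its columns belonged to other samples. Lower quartiles lay between 4.93 and 5.02 on the 15 reporter arrays and between 5.61 and 5.68 on the 6 knockout arrays, so that the 2 genotypes may have been normalized separately and levels set across genotypes are limited by this. Arrays give no read depth, and the number of arrays limits the precision.

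Clusters were named from an annotation table of the array. Of the 23332 clusters, 14996 carried 1 gene symbol, 1019 several symbols and 7317 none. Gene symbols were compared with a current gene table through gene identifiers: 14941 clusters matched and 0 symbols changed. For 135 genes with more than 1 cluster, the cluster with the highest mean over all arrays was kept, which left 14860 genes for testing. The build of the annotation differs from mm8, and no coordinates were used. Foxp3 shares its cluster with Flicr, a non-coding RNA gene next to it, and this cluster was tested among all 23332 clusters. Ctla4, Ikzf4, Lrrc32 and Tcf7 had no cluster of their own in the annotation used and were not analysed here. Some further genes are not reported here.

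Differences were tested with limma 3.58.1 in R 4.3.3, as moderated tests on the deposited log2 values, 2-sided, with Benjamini-Hochberg adjustment over the 14860 genes and a call at an adjusted p under 0.05. The model held a mean for each of the 5 groups and a term for study number (1 or 2), which the labels give: reporter replicates 1 to 3 are study 1, and reporter replicates 4 and 5 and all knockout arrays are study 2. All 21 arrays entered 1 fit, so that the groups share an estimate of the spread. The 7 contrasts were each TGFB fraction of the reporter cells against untreated reporter cells, the fractions against each other, TGFB against untreated knockout cells, the untreated genotypes against each other, and the difference between the TGFB response of each reporter fraction and that of the knockout cells. Values with ± are standard errors of the log2 fold change from this fit, unless given as SD. The labels call the samples biological replicates without naming animals or cultures, so p-values measure the spread between these samples.

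A collection of 25 gene lists was fixed for T cell programmes and for other cell types: regulatory T cell signature, genes repressed by Foxp3, TGFB response, adenosine pathway, Th1, Th2, Th17, cytotoxic, follicular helper and co-inhibitory, anergy, IL-2 and STAT5, naive and homing, cell cycle, glycolysis, cholesterol synthesis, interferon response, stress and unfolded protein response, T cell identity, CD8 T cell, B cell, dendritic cell and macrophage, NK cell, granulocyte, erythroid and Y-linked. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 168 tests, and again with an estimated correlation. The CD8 T cell list has 2 measured genes and was not tested as a list. For each list, members past the threshold were counted with adjustment over all genes and also adjusted over the list alone. Of the 71 list calls at the preset correlation, 1 held with an estimated correlation, the Th2 list in knockout cells.

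The genes named in the text follow a rule. It allows Foxp3 and a fixed panel of regulatory and helper T cell genes. It also allows the 8 highest and 8 lowest log2 fold changes past the threshold of each contrast (without predicted genes and receptor segments). Up to 5 members of each list with the smallest p in that contrast, and members of lists of 8 or fewer genes, were allowed too. Not every gene that the rule allows is given a value. The groups, contrasts, model, lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were a model without study, a replicate block, leaving out the dimmest genes (a share of 0.333), quantile normalization, centring of each array on its median, a trended and robust variance prior, estimated array weights, all clusters, a minimum 2-fold change, each study alone, the arrays of the compared groups alone, and leaving out each array in turn. Leaving out 4 reporter arrays with an interquartile range under 2.5, a covariate for that range, the settings run on the Foxp3 and Flicr cluster, and a split of the untreated arrays into sets of 3 and 2 were added after seeing the data.

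The fit was tested on simulated data with 200 changed genes among 14860. In the contrasts of TGFB with untreated cells it called 82% of 2-fold changes in hCD2-positive, 89% in hCD2-negative and 66% in knockout cells, and 95% to 100% of 4-fold changes. For the differences between responses, it called 47% (hCD2-positive minus knockout) and 41% (hCD2-negative minus knockout) of 2-fold changes and 92% and 88% of 4-fold changes. False calls in these 5 contrasts numbered 6 to 13, among 142 to 197 calls. In simulated lists, camera called the 1 shifted list and 0 of 24 unchanged lists. The simulated noise was drawn independently for each gene and array, without correlation between genes and without arrays of narrow range. The simulations therefore do not show how many false calls, of genes or of lists, correlated genes or array range would give. The shares called hold for 200 changed genes. The adjusted threshold is stricter where fewer genes change, so these shares do not carry over to contrasts with few calls.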

Results

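Transcript levels were measured in cultured splenocytes of Marilyn mice, whose transgenic T cell receptor makes CD4 T cells that recognise a male antigen. Reporter cells carry human CD2 (hCD2) as a surface marker of the expression of Foxp3, the transcription factor that defines regulatory T cells. Knockout cells carry a disrupted Foxp3 gene, as their labels give it. Cells were activated without (untreated) or with transforming growth factor beta (TGFB), and reporter cells given TGFB were sorted into hCD2-positive and hCD2-negative fractions. Untreated reporter cells and all knockout cells are labelled CD4+CD2, which does not say whether mouse or human CD2 is meant. Each of the 3 reporter groups had 5 arrays and each of the 2 knockout groups had 3. Array medians ranged from 6.05 to 6.48 (log2) in reporter and from 6.83 to 7.08 in knockout samples, and interquartile ranges from 2.01 to 3.14 and from 2.33 to 2.94. Among the reporter arrays, 4 had an interquartile range under 2.5, all from TGFB groups: hCD2-negative replicates 1 (2.33), 3 (2.23) and 4 (2.47), and hCD2-positive replicate 3 (2.01). Knockout untreated replicates 1 (2.41) and 2 (2.38) and knockout TGFB replicate 1 (2.33) were also under 2.5. These knockout arrays were kept in the settings without the narrow arrays. Correlations across genes between arrays of 1 group lay between 0.926 and 0.991.

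**Figure D1:**
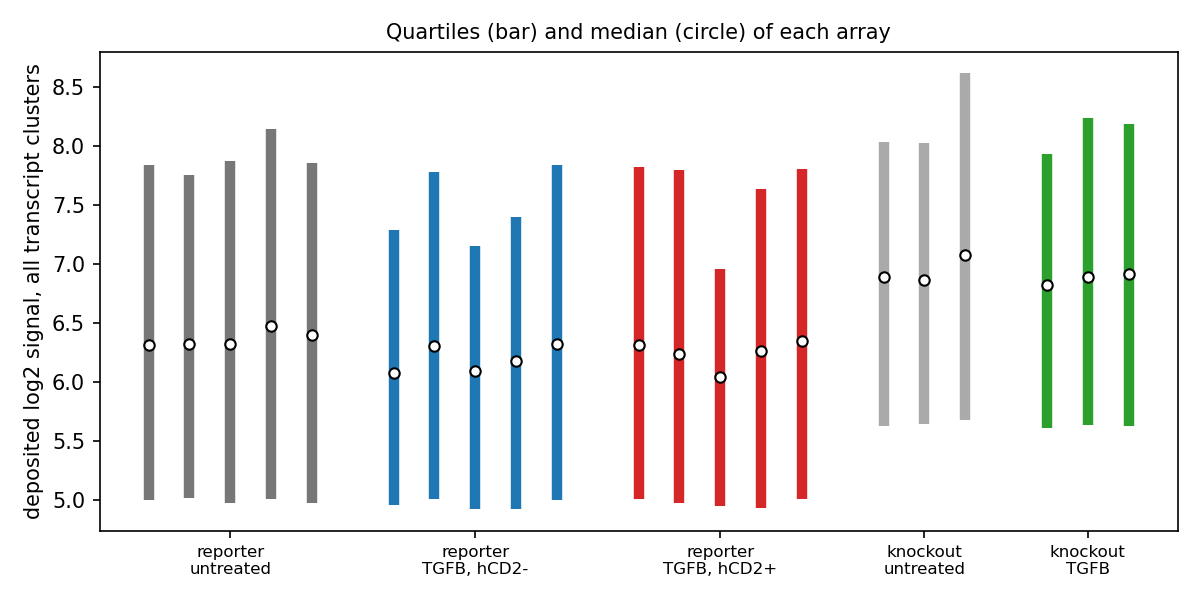
Lower quartile, median and upper quartile of the log2 values of each of the 21 arrays, by group. Lower quartiles are 4.93 to 5.02 on reporter arrays and 5.61 to 5.68 on knockout arrays, and hCD2-positive replicate 3 has the narrowest range (2.01).

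The transcript cluster annotated to both Foxp3 and Flicr was 20.6-fold higher in hCD2-positive TGFB cells than in untreated reporter cells, with means of 10.67 ± 1.02 and 6.30 ± 0.22 (log2, SD, n = 5 each). The log2 fold change was 4.36 ± 0.26 (limma adjusted p = 1.65e-08). In hCD2-negative cells the cluster averaged 6.72 ± 0.31 (SD, n = 5), a log2 difference from untreated cells of 0.42 (95% interval -0.13 to 0.96, limma adjusted p = 0.303). It was 15.4-fold higher in hCD2-positive than in hCD2-negative cells (log2 3.95, adjusted p = 3.48e-07). Within the hCD2-positive fraction, the 3 arrays of study 1 lay between 9.23 and 10.44 and the arrays of study 2 at 11.64 and 11.68.

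In knockout cells the same Foxp3 and Flicr cluster rose 3.05-fold with TGFB, from 6.94 ± 0.20 to 8.55 ± 0.32 (log2, SD, n = 3 each), a log2 fold change of 1.61 ± 0.34 (limma adjusted p = 0.0175). This call was lost without knockout untreated replicate 2 (log2 1.53, adjusted p = 0.0641) or 3 (1.56, 0.0705), and without knockout TGFB replicate 2 (1.43, 0.111) or 3 (1.64, 0.0668). The rise in hCD2-positive reporter cells exceeded that in knockout cells by 2.76 ± 0.43 (log2, limma adjusted p = 0.110), and quantile normalization gave 2.71 (adjusted p = 0.00655). Which part of the gene is disrupted, and whether the cluster's probes lie in it, are not given in the sources used here.

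**Figure D2:**
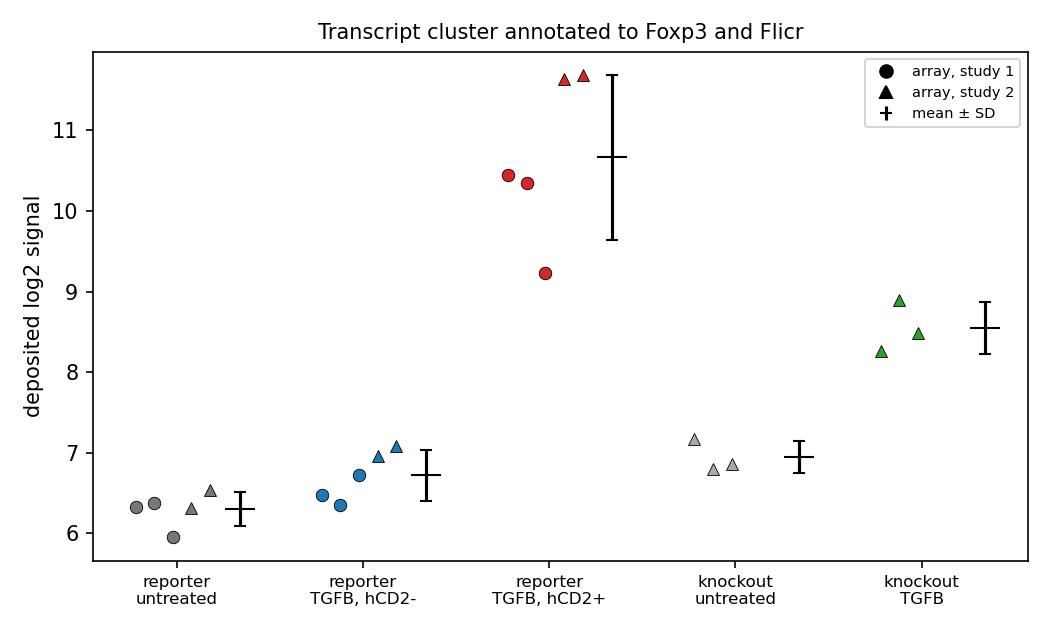
Log2 values of the transcript cluster annotated to Foxp3 and Flicr on each array, with group means and SD. The hCD2-positive arrays lie between 9.23 and 11.68, the knockout TGFB arrays between 8.26 and 8.90, and the arrays of the other 3 groups between 5.95 and 7.17.

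TGFB-treated hCD2-positive cells were compared with untreated reporter cells, a contrast that the study's design names. They had higher levels of Nt5e (CD73, an enzyme that makes extracellular adenosine), which rose 12-fold, Itgae (CD103, an integrin chain induced by TGFB) and Ikzf2 (Helios, a transcription factor of regulatory T cells). Their log2 fold changes were 3.59 ± 0.36 (adjusted p = 3.36e-06), 3.37 ± 0.38 (1.37e-05) and 3.06 ± 0.27 (8.86e-07). Genes for effector molecules fell: the granzyme gene Gzmb fell by 5.27 ± 0.57 on the log2 scale, the granzyme gene Gzma fell by 5.25 ± 0.43, and Csf2, the gene of the cytokine GM-CSF, fell by 5.17 ± 0.60. Csf2 averaged 9.65 ± 1.94 in untreated and 4.49 ± 0.27 in hCD2-positive cells (SD, n = 5). The latter mean lies under the lower quartile of the reporter arrays, so the size of the fall is uncertain. Other genes that rose were Ldlrad4 (log2 2.65), an inhibitor of TGFB signalling, Ift80 (2.57), the chemokine receptor gene Ccr6 (2.50), Stxbp6 (2.31), St6galnac3 (2.30), Nrp1 (2.04) and Tox (1.55). Epas1 (-4.32, limma adjusted p = 5.17e-13), Cyp11a1 (-4.09), Cdkn1a (-3.94), Tube1 (-3.81) and Gzmd (-3.72) fell, with Gzmd belonging to a family of near-identical granzyme genes whose probes may share signal. The hCD2-positive means of Cyp11a1 (4.90) and Gzmd (4.36) and the untreated mean of Ccr6 (4.07) also lie under that lower quartile.

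By gene group, the Th2 list had 7 of its 10 measured members lower and 0 higher, among them the cytokine genes Il24 (-3.89), Il13 (-3.06) and Il4 (-2.42) and the Th2 regulator Gata3 (-1.35); adjusted over the list alone the count was also 7. Its camera adjusted p was 3.4e-06, against an adjusted p = 0.125 with an estimated correlation. Of 14 Th1 genes 6 fell and 1 rose (7 and 1 adjusted over the list alone), with Il12rb2 at -3.74, Il12rb1 at -2.86, the Th1 regulator Tbx21 at -1.31 and Ifng at -0.95 (adjusted p = 0.0293). That list had an adjusted p = 0.0336 with camera and an adjusted p = 0.673 with an estimated correlation. Among 13 cytotoxic genes 6 fell and 1 rose (8 and 1 adjusted over the list alone), with an adjusted p = 0.0164 and an adjusted p = 0.585 with an estimated correlation. The IL-2 and STAT5 list had 10 of 13 lower (10 adjusted over the list alone), including Tnfrsf8 (-3.15) and the IL-2 receptor gene Il2ra (-1.10), with a camera adjusted p of 6.3e-09 and an adjusted p = 0.270 with an estimated correlation.

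Genes of growth and metabolism fell in hCD2-positive cells. In the cell cycle list 24 of 28 members were lower (28 adjusted over the list alone), including the mitotic kinase gene Cdk1 (-1.84) and Top2a (-1.79), with a camera adjusted p of 1e-15 and an adjusted p = 0.353 with an estimated correlation. In glycolysis 9 of 12 were lower (11 adjusted over the list alone), including Hk2 (-2.24) and the glucose transporter gene Slc2a3 (-1.88), with an adjusted p = 2e-08 and an adjusted p = 0.352 with an estimated correlation. In cholesterol synthesis 8 of 15 were lower (11 adjusted over the list alone), including Lss (-2.20) and Sqle (-1.70), with an adjusted p = 1.3e-07 and an adjusted p = 0.378 with an estimated correlation. In the stress and unfolded protein list 11 of 15 were lower (11 adjusted over the list alone), including the asparagine synthetase gene Asns (-2.96), with an adjusted p = 1.3e-08 and an adjusted p = 0.216 with an estimated correlation.

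The TGFB response list was mixed in hCD2-positive cells, with 7 of 26 members higher and 3 lower (7 and 4 adjusted over the list alone; 12 and 3 after quantile normalization). The inhibitory SMAD gene Smad7 (1.10, adjusted p = 0.00656) and Skil (0.94, adjusted p = 0.0315) rose, and Id2 (-2.83) fell; the list had an adjusted p = 0.0252 and an adjusted p = 0.711 with an estimated correlation. In the naive and homing list 5 of 12 rose, among them S1pr1 (2.26), Ccr7 (1.74) and Klf2 (1.34), which guide lymphocyte traffic, and 2 fell (5 and 3 adjusted over the list alone), with an adjusted p = 0.0184 and an adjusted p = 0.610 with an estimated correlation. The regulatory T cell signature had 6 of 22 members higher and 6 lower (7 and 7 adjusted over the list alone; camera adjusted p = 0.509): beside the higher Nt5e, Itgae, Ikzf2 and Nrp1 stood lower Il10 (-3.51), Entpd1 (-1.55) and Il2ra. The hCD2-positive mean of Il10 (3.76) lies under the lower quartile of the reporter arrays, so the size of its fall is uncertain. Cd4 differed by -0.37 (limma adjusted p = 0.314).

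In all, limma called 1725 genes in hCD2-positive against untreated cells, 289 higher and 1436 lower, and 745 of them at least 2-fold. Of 43 called genes, a part of those the naming rule allows, every hCD2-positive array lay beyond every untreated array in 37, and of all 1725 in 925. Over the 14860 genes tested, called or not, the arrays separated in 1090 (7.34%), where chance gives 0.794%. The balance of directions depended on scaling: 83.2% of calls were lower on the deposited values, and 52.7% of 2638 calls (1247 higher, 1391 lower) after quantile normalization. Within study 1 alone 279 genes were called (29 higher, 250 lower), and within study 2 alone 208 (42 higher, 166 lower).

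TGFB-treated hCD2-negative cells, which carried little of the Foxp3 and Flicr cluster, were compared with the same untreated cells. Kit, a growth factor receptor gene, rose 21.5-fold (log2 4.43 ± 0.21, adjusted p = 2.08e-10), and Itgae (3.85), Nt5e (3.19) and Ikzf2 (3.04, adjusted p = 7.39e-07) rose here too. Cd8a, which encodes a chain of the CD8 co-receptor, rose by 2.44 ± 0.27 (adjusted p = 6.82e-06), from 6.33 to 8.77. Csf2 fell by 5.06 on the log2 scale, Gzmb by 4.94 and Epas1 by 4.42 (adjusted p = 3.48e-13), and Il2ra fell by 2.54 ± 0.20 (adjusted p = 1.74e-07). Olfr46 (2.50, from an untreated mean of 3.70 that lies under the lower quartile of the arrays), Car2 (2.46) and Ldlrad4 (2.40) were also higher, and Cdkn1a (-4.36), Cyp11a1 (-4.29), Ifitm3 (-4.26), Tube1 (-4.23) and Gzmd (-4.03) lower. The hCD2-negative means of Csf2 (4.59), Cyp11a1 (4.70) and Gzmd (4.04), and of Ccr4 (3.66) and Il10 (3.63) named below, lie under that quartile too. The size of these falls is uncertain.

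Proliferation genes were lower throughout the cell cycle list in hCD2-negative cells, with 28 of 28 members called (28 adjusted over the list alone), including Mki67 (-3.44) and Top2a (-3.17); quantile normalization called 27. Its camera adjusted p was 3.6e-20, with an adjusted p = 0.294 with an estimated correlation. In the IL-2 and STAT5 list 12 of 13 were lower (12 adjusted over the list alone), including Socs2 (-3.24) and Cish (-2.57), which STAT5 induces, with an adjusted p = 5.3e-14 and an adjusted p = 0.125 with an estimated correlation. Of the Th2 list 7 of 10 fell (7 adjusted over the list alone), with Ccr4 at -3.94, Il24 at -3.83, Il4 at -2.63 and Gata3 at -2.22, an adjusted p = 2.6e-06 and an adjusted p = 0.125 with an estimated correlation. In the Th1 list 6 of 14 fell, among them Il12rb1 (-3.15), and 2 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.162). Cytotoxic genes were lower for 6 of 13 and higher for 0 (6 and 1 adjusted over the list alone), with Gzma at -2.17 and a camera adjusted p of 0.0936.

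The metabolic lists were lower in hCD2-negative cells as well: glycolysis in 10 of 12 members (11 adjusted over the list alone; Hk2 -2.35), cholesterol synthesis in 13 of 15 (14; Lss -2.13, and 7 after quantile normalization) and stress and unfolded protein in 12 of 15 (12; Asns -3.02). Their camera adjusted p values were 1.3e-07, 3e-08 and 2.8e-08, with adjusted p values of 0.353, 0.353 and 0.226 with an estimated correlation. The regulatory T cell signature had 12 of 22 lower, including Tnfrsf4 (-2.68), Entpd1 (-2.52) and Il10 (-3.65), and 3 higher (12 and 3 adjusted over the list alone), with an adjusted p = 0.0417 and an adjusted p = 0.673 with an estimated correlation. The TGFB response list had 4 of 26 higher and 4 lower (6 and 4 adjusted over the list alone; 11 and 4 after quantile normalization; camera adjusted p = 0.145), with Smad7 at 1.05 and Skil at 0.81 (adjusted p = 0.0473). In the naive and homing list 4 of 12 rose, including S1pr1 (1.52) and Ccr7 (1.45), and 4 fell (5 and 4 adjusted over the list alone; 8 and 2 after quantile normalization; camera adjusted p = 0.0862). Cd4 differed by -0.51 (adjusted p = 0.117), and Cd8b1, the other CD8 chain, was lower by -0.74 (adjusted p = 0.0152; -0.25, adjusted p = 0.165, after quantile normalization).

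Limma called 2811 genes in this contrast, 304 higher and 2507 lower, of which 1076 changed at least 2-fold. Leaving out 1 array at a time gave 1817 to 3794 calls. Of 38 called genes, a part of those the naming rule allows, 31 had every array of 1 group beyond every array of the other, and 1381 of all 2811 did. Over all 14860 genes 1506 did (10.1%, where chance gives 0.794%). Lower calls made up 89.2% on the deposited values and 50.7% of 3401 calls (1676 higher, 1725 lower) after quantile normalization. Without the 4 arrays of narrow range, which leaves hCD2-negative replicates 2 and 5, 1010 genes were called. Fewer arrays and array range cannot be told apart as the reason for that lower count. With array weights 5817 were called (963 higher, 4854 lower). Study 1 alone gave 532 (24 higher, 508 lower) and study 2 alone 441 (44 higher, 397 lower).

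The sorted fractions of the TGFB cultures were then compared with each other. Beside the Foxp3 and Flicr cluster, hCD2-positive cells had more Socs2 (log2 2.64 ± 0.30, adjusted p = 0.000369), Pim1 (2.05), Il2ra (1.44 ± 0.20, adjusted p = 0.00273) and Cish (1.23), which are targets of IL-2 signalling through STAT5. They also had more Stxbp6 (2.26), the chemokine receptor gene Ccr4 (2.12), Ramp1 (1.85), Tlr1 (1.79), Cd81 (1.62), Fsd1l (1.50) and Igfbp4 (1.11). They had less Gzma (-3.08 ± 0.43, adjusted p = 0.00273), Kit (-2.16 ± 0.21, adjusted p = 8.93e-05) and Cd8a (-1.76 ± 0.27, adjusted p = 0.00583). Socs2 averaged 10.55 in hCD2-positive, 7.90 in hCD2-negative and 11.15 in untreated cells, and Kit 8.20, 10.36 and 5.93. The hCD2-negative means of Ccr4 (3.66) and Fsd1l (4.14) lie under the lower quartile of the reporter arrays, so the size of their differences is uncertain.

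In the IL-2 and STAT5 list 4 of 13 genes were higher and 0 lower in hCD2-positive than in hCD2-negative cells (4 adjusted over the list alone), with a camera adjusted p of 1.6e-14 and an adjusted p = 0.125 with an estimated correlation. The regulatory T cell signature had 2 of 22 members higher over all genes and 12 adjusted over the list alone (7 after quantile normalization), with an adjusted p = 1.8e-17 and an adjusted p = 0.119 with an estimated correlation. Its members Izumo1r (log2 1.12, adjusted p = 0.0630), Capg (1.35, 0.140), Nrp1 (1.56, 0.211), Entpd1 (0.97, 0.636) and Tnfrsf4 (2.29-fold higher, 0.0567) missed the threshold. For Nt5e, Itgae and Ikzf2 the log2 differences were 0.40, -0.48 and 0.02. In the cell cycle list limma called 0 of 28 genes, 10 at an unadjusted p under 0.05 and 8 adjusted over the list alone, with a camera adjusted p of 3.2e-16 and an adjusted p = 0.352 with an estimated correlation; Top2a differed by 1.38 (adjusted p = 0.0630) and Mki67 by 1.61 (adjusted p = 0.172).

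In this contrast limma called 23 genes, 19 higher and 4 lower, and quantile normalization gave 136 (94 higher, 42 lower; 30.9% lower against 17.4%). Array weights gave 3489 (3071 higher, 418 lower), but single arrays weighed most in that fit. The weights were 3.89 for hCD2-positive replicate 5 (0.14 to 1.21 for its other replicates) and 2.66 for hCD2-negative replicate 4 (0.39 to 0.99). Of 14 called genes under the naming rule, 9 separated all arrays, and of the 23 genes 15 did. Over all 14860 genes 99 did (0.666%), no more than the 0.794% that chance gives, and 216 (1.45%) after quantile normalization. Within study 1 limma called 0 genes (324 at an unadjusted p under 0.05) and within study 2 also 0 (242). The 324 and 242 lie below the share of 0.05 of 14860 genes that chance gives. With the 10 sorted arrays alone limma called 4, Socs2, Stxbp6, Kit and Igfbp4. Without the 4 narrow arrays, which leaves hCD2-negative replicates 2 and 5, 9 genes were called, and without hCD2-positive replicate 3 alone 88.

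TGFB was also compared with no treatment in knockout cells. Itgae (log2 4.57 ± 0.49, adjusted p = 2.52e-05), Kit (4.21 ± 0.27, 3.79e-08), Nt5e (3.93) and Ikzf2 (3.26 ± 0.35, adjusted p = 2.52e-05) rose in these cells too. So did the chemokine genes Xcl1 (3.96) and Ccl5 (3.41), Cd7 (3.65), Car2 (3.24), Cd8a (2.47 ± 0.35, adjusted p = 0.000386) and Cd160 (1.85). Csf2 fell by 5.50 ± 0.77 on the log2 scale (adjusted p = 0.000362) and Il10, the gene of an anti-inflammatory cytokine, by 5.11 ± 0.70 (adjusted p = 0.000266). Gzmd (-4.89), Epas1 (-4.57), Cyp11a1 (-4.32) and Ecm1 (-3.85) also fell. The knockout TGFB means of Il10 (4.10) and Gzmd (4.47) lie under the lower quartile of the knockout arrays, so the size of their falls is uncertain. Gzmb differed by -2.47 (adjusted p = 0.0904), Ifng by -1.13 (0.112), Cd8b1 by -0.20 (0.952) and Cd4 by -0.03 (0.996).

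The Th2 list had 6 of 10 members lower in knockout cells (8 adjusted over the list alone), with Il24 at -4.13, Il13 at -3.96, Il4 at -2.79 and Gata3 at -1.91; its camera adjusted p of 8.3e-16 was an adjusted p = 0.006 with an estimated correlation, below 0.05. In the IL-2 and STAT5 list 7 of 13 fell (10 adjusted over the list alone), including Tnfrsf8 (-3.33) and Il2ra (-1.49), with an adjusted p = 1e-13 and an adjusted p = 0.125 with an estimated correlation. The TGFB response list had 4 of 26 higher and 1 lower (8 and 3 adjusted over the list alone; 10 and 3 after quantile normalization), with Ldlrad4 at 2.81, Smad7 at 1.26 (adjusted p = 0.0407) and Id2 at -2.13, an adjusted p = 0.000645 and an adjusted p = 0.585 with an estimated correlation; Skil differed by 1.06 (adjusted p = 0.149). In the stress and unfolded protein list 6 of 15 fell (11 adjusted over the list alone; 10 after quantile normalization; Asns -2.37), with an adjusted p = 5.4e-12 and an adjusted p = 0.125 with an estimated correlation. In the naive and homing list 3 of 12 rose, including Ccr7 (2.45) and S1pr1 (2.14), and 1 fell (5 and 2 adjusted over the list alone; 6 and 2 after quantile normalization), with an adjusted p = 0.000644 and an adjusted p = 0.533 with an estimated correlation.

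In the growth lists limma called, with 3 knockout arrays per group, 2 of 28 in the cell cycle list (2 adjusted over the list alone), Tyms (-1.14) and E2f1 (-1.04), 1 of 12 in glycolysis (2) and 1 of 15 in cholesterol synthesis (4), Lss (-1.37), all lower. After quantile normalization 5, 3 and 4 were lower, and 1 glycolysis gene was higher. Their camera adjusted p values were 4.5e-06, 0.0439 and 0.000154, with adjusted p values of 0.585, 0.711 and 0.544 with an estimated correlation. The regulatory T cell signature had 3 of 22 higher and 7 lower (3 and 9 adjusted over the list alone; camera adjusted p = 0.134), with Entpd1 at -1.70. Th1 genes were higher for 2 and lower for 1 of 14 (2 and 3 adjusted over the list alone; camera adjusted p = 0.664), with Il12rb1 at -2.31, and cytotoxic genes higher for 1 and lower for 2 of 13 (2 and 4, and also 2 and 4 after quantile normalization; camera adjusted p = 0.0529). Tox rose by 2.09.

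Limma called 408 genes in knockout cells, 133 higher and 275 lower. All of 34 called genes that were checked, a part of those the naming rule allows, and 407 of the 408 separated all 6 arrays. Over all 14860 genes 2437 did (16.4%), where chance gives 10%. Lower calls made up 67.4%, against 46.8% of 1612 calls (858 higher, 754 lower) after quantile normalization and 39.1% of 1508 (918 higher, 590 lower) with array weights. Counts moved by more than 1.5 times without untreated replicate 3, where lower calls were no longer the majority (266, 138 higher and 128 lower), and without TGFB replicates 1 (238), 2 (221) or 3 (233). All knockout arrays belong to study 2, so that no comparison between studies can be had for them.

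**Figure D3:**
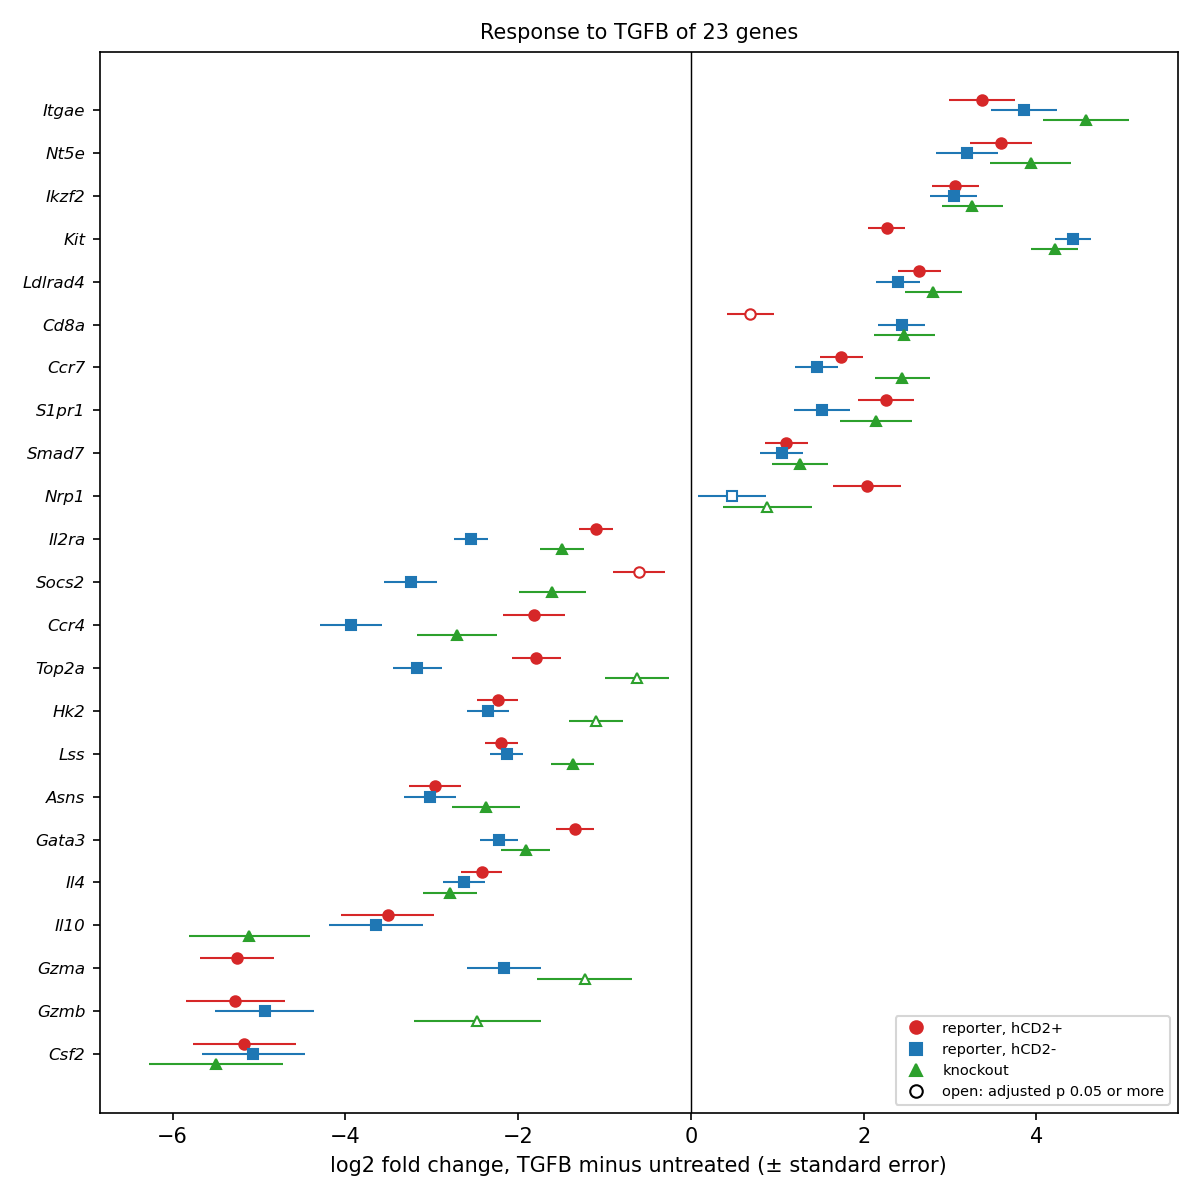
Log2 fold change of TGFB against untreated (± SE) for 23 genes named in any of the comparisons, in hCD2-positive, hCD2-negative and knockout cells, with open symbols at an adjusted p of 0.05 or more. Itgae lies between 3.37 and 4.57 and Csf2 between -5.50 and -5.06 in the 3 comparisons, while Cd8a is called in hCD2-negative (2.44) and knockout cells (2.47) and stands at 0.69 in hCD2-positive cells (adjusted p = 0.117; 0.84, adjusted p = 0.0212, after quantile normalization).

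The responses to TGFB were compared across genotypes, the comparison that bears on what depends on Foxp3. Nt5e, Itgae and Ikzf2 rose in all 3 TGFB groups, and their response in hCD2-positive cells differed from that in knockout cells by -0.34, -1.21 and -0.19, and in hCD2-negative cells by -0.74, -0.72 and -0.21, none of them called. Of the 133 genes higher in knockout cells, 98 were also called higher in hCD2-negative cells and 88 in hCD2-positive cells, where independent calls would share 2.72 and 2.59. Of the 275 lower genes, 268 and 257 were shared (46.4 and 26.6 if independent), and 0 genes were called in opposite directions. Across the 14860 genes, which are not independent replicates, log2 fold changes in hCD2-negative and knockout cells correlated with r = 0.776 (Spearman's rho 0.653), and those in hCD2-positive and knockout cells with r = 0.794 (rho 0.671).

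The hCD2-positive and hCD2-negative responses correlated with r = 0.923 (rho 0.901) but share their untreated arrays, which alone gave r = 0.499 in 50 simulations without any effect; with separate untreated arrays, r was 0.810. Over the 408 genes called in knockout cells, the slope of the hCD2-negative on the knockout response was 0.937 and that of the hCD2-positive response 0.845. These slopes were taken over genes selected in knockout cells, and r for hCD2-negative and knockout cells was 0.554 without knockout untreated replicate 3.

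**Figure D4:**
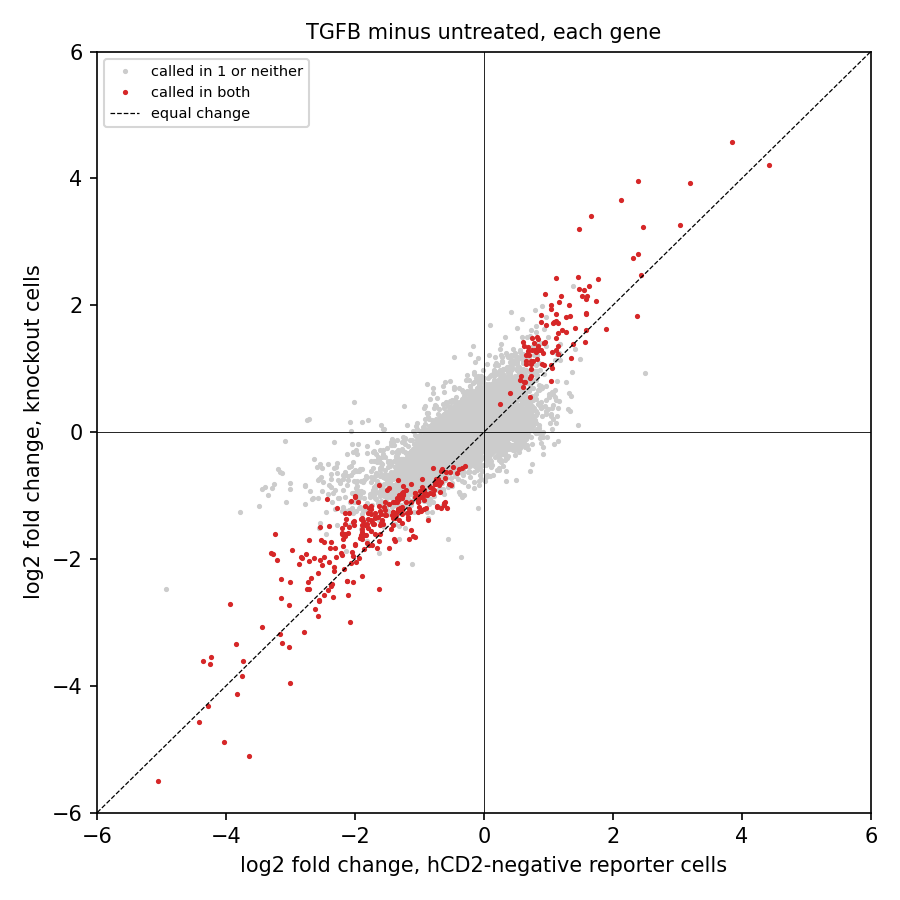
Log2 fold change with TGFB in knockout cells (vertical axis) against that in hCD2-negative reporter cells (horizontal axis), 1 point per gene for 14860 genes. Pearson's r across genes is 0.776, and 98 genes are called higher and 268 lower in both.

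The difference between responses was then tested. Igfbp4, the gene of a binding protein of insulin-like growth factors, differed between hCD2-negative and knockout cells by -2.50 ± 0.33 (log2, limma adjusted p = 0.00877): it averaged 9.52 ± 0.51 and 7.50 ± 0.13 in untreated and hCD2-negative reporter cells (SD, n = 5) and 9.09 ± 0.28 and 9.56 ± 0.36 in untreated and TGFB-treated knockout cells (SD, n = 3). That was the 1 gene called, with 550 at an unadjusted p under 0.05. The call was lost after quantile normalization (-2.14, adjusted p = 0.203), with study 2 alone, and without the narrow arrays (-2.42, adjusted p = 0.461). The count depended on the setting and on single arrays: array weights gave 3293 calls (278 higher, 3015 lower), and leaving out knockout untreated replicate 3 gave 55 (1 higher, 54 lower). Without reporter untreated replicate 1 or knockout untreated replicate 1 there were 2, and without knockout untreated replicate 2 or knockout TGFB replicate 2 or 3 there were 0. For hCD2-positive minus knockout, limma called 0 genes, with 375 at an unadjusted p under 0.05, 13 after quantile normalization (1 higher, 12 lower) and 68 with array weights (5 higher, 63 lower). The counts of 375 and 550 at an unadjusted p under 0.05 lie below what chance gives, a share of 0.05 of 14860 genes. Gzma differed by -4.02 ± 0.70 (adjusted p = 0.113; -3.91, adjusted p = 0.0243, after quantile normalization), Cd160 by -1.84 (0.367; -2.06, adjusted p = 0.0275, after quantile normalization) and Cd8a by -1.78 (0.874).

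Among the lists, the response of cell cycle genes differed between hCD2-negative and knockout cells by a median of -1.13 (12 of 28 lower adjusted over the list alone, 0 over all genes and 16 at an unadjusted p under 0.05 in limma), with a camera adjusted p of 3e-22 and an adjusted p = 0.270 with an estimated correlation; Top2a differed by -2.54 ± 0.46 (adjusted p = 0.162). Glycolysis genes differed by a median of -1.08 in hCD2-negative cells (9 of 12 adjusted over the list alone) and -0.93 in hCD2-positive cells (4 of 12), but limma called 0 of 12 over all genes in either (9 and 8 at an unadjusted p under 0.05). Camera gave them adjusted p values of 4.2e-09 and 7.4e-10, and adjusted p values of 0.323 and 0.294 with an estimated correlation. Reporter arrays with an interquartile range under 2.5 were all TGFB arrays. In knockout cells they were untreated replicates 1 (2.41) and 2 (2.38) and TGFB replicate 1 (2.33). Whether array range gave part of these list differences was not tested. With 3 arrays per knockout group, simulated 2-fold differences between responses were called in 47% (hCD2-positive) and 41% (hCD2-negative), so a difference of that size in a single gene was often not detectable. Those simulations held 200 changed genes and gave 145 and 142 calls, where the real contrasts had 0 and 1. With fewer calls the adjusted threshold is stricter, so larger differences could be missed too. Top2a at -2.54 and, for hCD2-positive cells, the Foxp3 and Flicr cluster at 2.76 were not called.

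Untreated knockout and untreated reporter cells were compared to see how the genotypes differed before TGFB. Against a median shift of all genes of 0.44, knockout cells had higher Ccl20, a chemokine gene (1.42 ± 0.16, adjusted p = 2.54e-06; 0.89, adjusted p = 0.0272, after quantile normalization), Gzma (1.97), Il13 (1.67) and Entpd1 (1.57), and lower Nasp (-1.17), Nrn1 (-1.15) and Ndufb9 (-1.01). After quantile normalization Gzma was at 1.75 (adjusted p = 0.0498), Il13 at 1.48, Entpd1 at 1.35, Nasp at -1.53, Ndufb9 at -1.18 and Nrn1, which lost its call, at -1.29 (adjusted p = 0.0544). The values of Nrn1 and Ndufb9 rest largely on the study term: their means were 9.13 and 8.30 in knockout and 9.72 and 8.54 in reporter cells, with 0 of 3 knockout arrays below all reporter arrays, and without the term they differed by -0.59 (adjusted p = 0.286) and -0.24 (adjusted p = 0.723). With study 2 arrays alone Nasp (-0.97, adjusted p = 0.109), Nrn1 (-0.85, adjusted p = 0.0948) and Ndufb9 (-0.94, adjusted p = 0.0926) were not called. Centring of the arrays ended the calls of Gzma (1.48, adjusted p = 0.0842), Il13 (1.18, adjusted p = 0.0657) and Entpd1 (1.08, adjusted p = 0.0897). Olfr46 (2.54) and Vmn1r230 (2.44) were called higher, but their reporter means of 3.70 and 3.98 lie under the lower quartile of the reporter arrays, and that quartile differs between the genotypes, so the size of these differences is uncertain. After quantile normalization Vmn1r230 was at 1.72 (adjusted p = 0.0455), and Olfr46 lost its call (1.94, adjusted p = 0.110). The Foxp3 and Flicr cluster differed by 0.17 (adjusted p = 0.781), and by -0.27 after quantile normalization. That value rests largely on the study term: without the term the difference was 0.64 (adjusted p = 0.211), and with study 2 arrays alone 0.52 (adjusted p = 0.0774). Limma called 6846 genes, 6825 higher and 21 lower (6304 with study 2 alone; 0.307% lower), but 580 after quantile normalization, 267 higher and 313 lower (54.0% lower). Of the 6846, 6080 separated all arrays; over all 14860 genes 6572 did (44.2%), and 2642 (17.8%) after quantile normalization, where chance gives 3.57%.

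Markers of other cell types moved with this shift between genotypes: 8 of 9 B cell genes, 8 of 9 granulocyte genes, 4 of 4 erythroid genes, 10 of 14 dendritic cell and macrophage genes and 4 of 5 NK cell genes were higher in untreated knockout cells. After quantile normalization 0, 0, 0, 1 and 0 of them were called higher. Y-linked genes were higher in 2 of 3 on deposited values and in 0 after quantile normalization.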

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

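The test of scaling by quantile normalization, the one that leaves out the 4 narrow arrays and the one with array range as a covariate were chosen only after the share of lower calls or the array ranges had been seen. Of 234 sets of values tested in groups of 5, 14 had an array far from the others, where chance gives about 1 in 20 (11.7). Of these 14, 8 were on hCD2-positive replicate 3: the array's interquartile range of 2.01 (2.70 to 2.82 on the other arrays of its group), Il12rb1 at 6.29 (7.30 to 7.59), Slc2a3 at 7.68 (8.84 to 9.27), Cd4 at 9.27 (10.34 to 10.66), Cd8b1 at 7.98 (8.90 to 9.07), Tlr1 at 8.03 (9.18 to 9.27), Capg at 7.31 (8.59 to 9.08) and Ecm1 at 7.13 (8.11 to 8.26). In hCD2-negative cells Epas1 was 5.49 on replicate 1 (5.77 to 5.86), Cd8b1 9.49 on replicate 2 (8.77 to 8.96) and Mki67 4.93 on replicate 4 (5.98 to 6.34). In untreated reporter cells Il12rb1 was 10.65 (9.82 to 10.05) and Cd160 6.58 (5.62 to 5.67) on replicate 4, and Tube1 8.87 on replicate 5 (10.18 to 10.71).

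More genes were called lower than higher after TGFB in both reporter fractions, 83.2% of the hCD2-positive and 89.2% of the hCD2-negative calls; without the 4 arrays of narrow range the shares were 70.0% and 70.8%, between the bounds set for and against those arrays as the cause. With the interquartile range of each array as a covariate they were 52.1% (1271 higher, 1383 lower) and 54.6% (1192 higher, 1434 lower), which goes with array range as a source, but all 4 narrow arrays are TGFB arrays, so that range and treatment are partly confounded and this stays open. After quantile normalization the shares were 52.7% and 50.7%, but this method gives all arrays 1 distribution and so pushes the directions towards balance. In hCD2-positive cells it left 1391 lower calls beside 1436 and raised the higher calls from 289 to 1247, in hCD2-negative cells 1725 beside 2507 and from 304 to 1676. Array-wide scaling in the deposited values and a global fall of transcripts with TGFB cannot be told apart by it, and the latter was not tested.

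The response of Igfbp4 to TGFB differed between hCD2-negative reporter and knockout cells in the test of the difference itself (-2.50 on the log2 scale). That call was lost after quantile normalization, with study 2 alone, without the narrow arrays and without some single knockout arrays. Signals were also found in clusters that the comparisons of genes did not use. Among 7317 clusters without a gene name, limma called 386 in hCD2-positive and 662 in hCD2-negative against untreated cells, 3 between the fractions and 44 in knockout cells. Among 1019 clusters annotated to several genes it called 86, 131, 2 and 15, including a cluster of Lilrb4a and Lilr4b (-3.08 in hCD2-positive, -3.76 in hCD2-negative and -2.37 in knockout cells). A cluster of Gzmg and Gzmd stood at -3.41, -3.46 and -4.58.

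Other splits of the samples into groups of the same sizes were fitted in the same way. For hCD2-positive against untreated cells 1 of 100 splits, the real one, gave as many calls (real 1725, highest other 1345). The shares were 2 of 100 for hCD2-negative cells (real 2811, highest other 3153) and 1 of 56 for the untreated genotypes (real 6846, highest other 41). Counts as large were thus rare among such splits, which does not exclude chance, and another hCD2-negative split gave more calls than the real one. The split with 3153 calls exchanged 1 array of each group and kept the 3 narrow arrays together, as the real one does; of the 17 splits drawn that keep them together it was the 1 that called any gene. Between the fractions 4 of 100 splits gave 23 or more calls; the highest other gave 6665, which points to a structure of the samples beside the sort. That split had all 4 narrow arrays in 1 group; of the 4 splits with them together 2 called any gene (1330 and 6665), and of 95 with them in both groups 4 did (at most 2489), which leaves the part of array range in it open. For knockout cells the 10 possible splits are too few for a share under 0.05 (real 408, highest other 1). For the difference of hCD2-negative minus knockout 4 of 100 splits gave 1 gene or more (real 1, highest other 3976). For hCD2-positive minus knockout the real count was 0, which all 100 of 100 splits reach by construction, so that the splits decide nothing there (highest other 1342). What gave the high counts under other splits of these differences was not tested.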

How the results depend on the processing

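The settings without the 4 narrow arrays, with the interquartile range as a covariate and those for the Foxp3 and Flicr cluster were chosen only after the data were seen; the others were planned. Where no cause is named, the cause was not tested. Over all alternatives, the named genes that were followed, not all of those named, gave 3576 values with the Foxp3 and Flicr cluster. Of these, 3263 kept direction and side of the threshold, 223 lost a call, 64 gained one and 26 changed sign. Leaving out 1 array at a time gave 1628 of the values. With study 1 alone 34 of 110 values lost a call and 75 kept direction and side. With study 2 alone 34 of 133 lost a call and 98 kept both, with fewer samples in each study.

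Quantile normalization gave 2638 calls for hCD2-positive against untreated cells, 136 between the fractions, 1612 in knockout cells, 580 between untreated genotypes, and 13 and 0 for the differences of the hCD2-positive and hCD2-negative from the knockout response (788 at an unadjusted p under 0.05 for the last). Centring gave 49 between the fractions, 645 in knockout cells, 480 between genotypes, and 3 and 4 for the differences. Array weights gave 5817 for hCD2-negative cells, 3489 between the fractions, 1508 in knockout cells, and 68 and 3293 for the differences. The weights ran from 0.14 (hCD2-positive replicate 3) to 4.08 (knockout TGFB replicate 3), so that single arrays weighed heavily in these fits. Without the study term 11 were called between the fractions and 254 in knockout cells. Study 1 alone gave 279, 532 and 0 for the reporter contrasts and study 2 alone 208, 441 and 0, and 0 for the hCD2-negative difference (506 unadjusted), with fewer samples. The 506 lies below, and the 788 above, the share of 0.05 of 14860 genes that chance gives. The arrays of the compared groups alone gave 1127 for hCD2-positive cells, 4 between the fractions, and 1 and 2 for the differences. A minimum of 2-fold left 745, 1076 and, between genotypes, 1187 by construction, and leaving out the dimmest genes left 2606 between genotypes. Without the narrow arrays, replicates 2 and 5 were left of the hCD2-negative group. That setting gave 1010 for hCD2-negative cells, 9 between the fractions, 712 in knockout cells, and 1 and 0 for the differences. The covariate gave 2654 for hCD2-positive cells, 134 between the fractions, 1830 in knockout cells, 12228 between genotypes, and 1 and 2 for the differences. Of 71 list calls an estimated inter-gene correlation left 1, and list calls numbered 61 without the study term, 60 without the dimmest genes and 54 after quantile normalization. The correlation of hCD2-negative and knockout responses (0.776) was 0.747 (study 2 alone) to 0.828 (the covariate) in the settings run for it, which also were no study term, the dimmest genes left out, quantile normalization and no narrow arrays.

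Leaving out 1 array at a time gave 1218 to 1989 calls for hCD2-positive cells, 1817 to 3794 for hCD2-negative cells (1817 without replicate 4 and 1857 without replicate 3 of that group), 15 (without hCD2-positive replicate 1) to 88 (without hCD2-positive replicate 3) between the fractions, 221 to 383 in knockout cells (266 without untreated replicate 3, and 238, 221 and 233 without TGFB replicates 1, 2 and 3), and 6165 to 6766 between genotypes. The hCD2-positive difference had 0 to 1 calls (1 without hCD2-positive replicate 3). The hCD2-negative difference had 0 (without knockout untreated replicate 2 or knockout TGFB replicate 2 or 3) to 55 (without knockout untreated replicate 3), and 2 without reporter untreated replicate 1 or knockout untreated replicate 1. The correlation ranged from 0.554 (without knockout untreated replicate 3) to 0.832.

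A replicate block, with arrays of 1 genotype and number as a pair, gave 1982, 3388, 26 and 516 calls for the 4 contrasts within a genotype, 0 and 1 for the differences, 57 list calls of 144 tests and r = 0.776, and could not be fitted for the untreated genotypes. The pairing was checked on residuals with study removed: arrays of equal number correlated by -0.37 to -0.06 between untreated and hCD2-negative cells, -0.22 to -0.01 between untreated and hCD2-positive cells, -0.30 to 0.71 between the fractions and -0.18 to 0.58 in knockout cells. Over 0.1 were 0 of 5, 0 of 5, 4 of 5 and 2 of 3 pairs, and 0, 0, 2 and 1 arrays correlated best with their own number. As no comparison had every pair over 0.1, the numbers were not taken as pairs, but arrays of the fractions may share a culture, which the labels do not say; the block gave 26 calls there against 23.

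Signs changed for values near 0. Ikzf2 between the fractions (0.02) was -0.13 after quantile normalization, -0.03 after centring, -0.012 with array weights, -0.12 in study 1, -0.03 without the narrow arrays, -0.092 with the covariate, and -0.17 to 0.24 without 1 array. Cd4 in knockout cells (-0.03) was 0.15 after quantile normalization, 0.047 after centring, 0.051 with array weights, 0.069 with the covariate, and -0.11 to 0.085 without 1 array. The Ikzf2 differences from knockout (-0.19 and -0.21) were 0.036 and 0.066 without the narrow arrays and 0.011 and 0.10 with the covariate, and the first was -0.39 to 0.020 without 1 array. The Foxp3 and Flicr cluster between genotypes (0.17) was -0.27 after quantile normalization, -0.34 after centring, 0.64 without the study term, 0.52 with study 2 arrays alone and -0.031 to 0.24 without 1 array. Ikzf2 (9.52 in hCD2-positive cells) and Cd4 (11.20 in untreated knockout cells) are not dim, so their changes of sign go with differences near 0. Apart from these, genes near background limit what these arrays show, since a small change there may move with the scaling.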

Other observations

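The tests of Cd8a after quantile normalization, of the brightness of Cd8b1, and of intact Foxp3 by genes chosen on other arrays were chosen only after the results had been seen. Other fixed lists moved with TGFB as follows, given for hCD2-positive, hCD2-negative and knockout cells in that order. In the follicular helper and co-inhibitory list 3, 3 and 3 of 13 genes rose and 2, 2 and 1 fell (3, 3 and 4 rose and 2, 3 and 2 fell adjusted over the list alone): Bcl6, the regulator of follicular helper cells, rose by 1.13, 1.58 and 1.86, and the inhibitory receptor gene Havcr2 fell by 2.17, 2.11 and 2.58 on the log2 scale. In the anergy list 6, 4 and 2 of 14 rose and 2, 2 and 1 fell, with Nr4a3, an early gene of receptor signalling, at 0.90, 0.75 and 1.29 and Rnf128 at -1.07, -1.03 and -1.01; adjusted over the list alone 6, 4 and 4 rose and 3, 2 and 1 fell, and 7, 6 and 5 rose after quantile normalization. In the Th17 list 3, 3 and 1 of 12 rose and 4, 4 and 2 fell (3, 3 and 2 and 4, 4 and 3 adjusted over the list alone), with the AP-1 factor gene Batf at -2.09, -2.63 and -1.99 and the nuclear receptor gene Rora at 0.68, 0.61 and 1.42. The adenosine list had 1 of 9 higher and 2 lower in each (1, 2 and 2 higher and 3, 4 and 2 lower adjusted over the list alone; 3, 4 and 2 higher after quantile normalization), Nt5e up and Entpd1 down in all 3. Among genes repressed by Foxp3, 6, 5 and 3 of 10 fell and 0 rose (7, 5 and 4 adjusted over the list alone); quantile normalization called 2, 4 and 2 of them higher and 5, 4 and 4 lower. In the interferon list 1, 4 and 1 of 12 fell (1, 4 and 1 adjusted over the list alone; 0, 1 and 2 higher after quantile normalization), with the antiviral gene Mx1 at -2.41, -2.37 and -2.42.

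The camera adjusted p values of these lists, in the same order of cells, were 0.404, 0.305 and 0.00533 for the follicular helper list, 0.0454, 0.201 and 0.00132 for anergy, 0.860, 0.983 and 0.860 for Th17, 0.991, 0.918 and 0.860 for adenosine, 0.000396, 0.0340 and 0.147 for genes repressed by Foxp3, and 0.465, 0.110 and 0.305 for interferon. With an estimated correlation, those under 0.05 had adjusted p values of 0.544 (follicular helper), 0.711 and 0.552 (anergy), and 0.309 and 0.544 (repressed by Foxp3). T cell identity genes were called higher for 1, 0 and 0 of 11 and lower for 0, 2 and 0, and after quantile normalization higher for 5, 4 and 3 and lower for 1, 1 and 0. Among genes of other cell types, limma called 0 of 9 B cell genes (0, 0 and 1 at an unadjusted p under 0.05), 0 of 9 granulocyte genes (1, 1 and 0) and 0 of 3 Y-linked genes (0, 0 and 0). Of 4 erythroid genes 1, 0 and 0 were higher, and of 5 NK cell genes 1, 2 and 2 were lower (Eomes -0.67, -0.97 and -1.02, a gene that T cells express too). Of 14 dendritic cell and macrophage genes 2, 1 and 1 were higher and 1, 2 and 0 lower, with Ctss at 1.64, 1.12 and 1.86 and H2-Ab1 at -1.42 and -1.32 in the reporter fractions. Camera called 3 of these lists higher in hCD2-positive cells, B cell (adjusted p = 0.0399), granulocyte (0.0454) and dendritic cell and macrophage (0.0184), and the granulocyte list in hCD2-negative cells (0.0278), with median log2 fold changes of 0.086, 0.11, 0.11 and 0.086. With an estimated correlation these had adjusted p values of 0.455, 0.544, 0.184 and 0.544.

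Cd8a rose in hCD2-negative and knockout cells, which had been sorted for CD4. CD8 T cells would bring Cd8b1, which differed by -0.74 and -0.20, but Cd8b1 stood at 9.73 in untreated cells, above 96.3% of genes, a level that could hide a small share, so this explanation cannot be told apart. Dendritic cells with Cd8a would bring Cd74, H2-Aa and H2-Ab1, whose median difference was -0.23 and 0.42. The rise that such cells would need was not worked out, and in knockout cells the 95% interval of Cd74 reached 1.06. H2-Ab1 stood lower, at -1.32 and -0.62, but Ctss of the dendritic cell and macrophage list stood higher in both, as given above. This explanation therefore stays open too. Scaling is argued against by Cd8a at 2.70 and 2.76 after quantile normalization. A shift from ThPOK to Runx3, the factors that repress and permit Cd8a in CD4 T cells, was tested as a hypothesis. Zbtb7b, the gene of ThPOK, stood at -1.12 (limma adjusted p = 0.000188) and -0.74 (0.101), but Runx3 at -0.21 and 0.19 (0.589 and 0.983). After quantile normalization Zbtb7b stood at -0.62 (limma adjusted p = 0.0011) and -0.595 (0.0192), and Runx3 at 0.27 and 0.36 (0.315 and 0.512). Zbtb7b also fell in hCD2-positive cells (-0.75, limma adjusted p = 0.00781), where Cd8a was not called on the deposited values. Runx3 stood at -0.78 there (limma adjusted p = 0.0546). The hypothesis stays open.

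The Foxp3 and Flicr cluster rose in knockout cells given TGFB, and quantile normalization left the rise (1.77, adjusted p = 0.000362), which argues against scaling. Cells with intact Foxp3 among them, at a share of 16.6%, would add a median of 0.32 to the 19 genes higher in hCD2-positive than in hCD2-negative cells. That share sets the knockout rise, from study 2 arrays, against the gap between the fractions over both studies. It also sets knockout arrays against reporter arrays, which may have been normalized separately. A higher scale on the knockout arrays would inflate the share and the rise expected from it. On study 2 arrays alone the hCD2-positive values were higher (11.64 and 11.68), so the share and the rise expected from it would be smaller. The median found, 0.82, decides nothing, since these genes were picked on the same hCD2-negative arrays. The 19 higher genes with the smallest p on study 1 arrays (0 of them called there) were then followed on study 2 arrays. Their median extra rise in knockout over hCD2-negative cells was 0.51 (standard error of this median 0.24). Genes of like brightness had 0.22 (bounds 0.057 and 0.38), which left an excess of 0.29, against 0.22 expected. After quantile normalization the median was 0.25 (standard error 0.23), against -0.018 (bounds -0.14 and 0.12). The excess there was 0.27, against 0.19 expected. Both medians lay above the upper bound for like brightness, which goes with such cells. But 12 of 19 genes were above 0, and the excess was given no standard error, so this explanation stays open. Transcription of the disrupted gene, or of Flicr, in cells without Foxp3 protein is a biological alternative that was not tested here.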
